A study of Mus musculus with 6 samples.

How the data were processed

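RNA was measured by sequencing in 6 libraries from wild-type C57BL/6 mice 2 months old. Each library came from the lens capsule with the lens epithelial cells left on it after the fiber cells had been taken out through the cornea, per the labels. Tissue was collected either directly after the operation (0 h, 3 libraries) or 24 h later (3 libraries). The series calls the libraries biological triplicates. How many animals or eyes went into a library is not given in the sources used here.

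RNA was extracted with an RNeasy kit and made into TruSeq libraries, per the labels' protocols. The labels name both a TruSeq RNA kit and a stranded TruSeq kit and 2 HiSeq models, so the kit and the instrument stay open. The submitters' processing notes name FastQC, Trim Galore 0.4.4, TopHat2 2.1.0, bedtools 2.17, SAMtools 1.4, HTSeq 0.6.1p1, edgeR 3.16.5 and the mm10 build. How strand was handled in counting and which annotation was used are not given in the sources used here, so reads from overlapping genes on opposite strands may not have been told apart. The authors deposited whole-number read counts per gene for each library, with the gene's symbol, chromosome, start, stop and length, per the file headers. The deposited RPKM values equal each gene's count divided by its length and by the library's summed gene counts, to within rounding, and were not used in any test. The deposited tables hold 24147 genes or gene copies, of which 5444 had 0 counts in all 6 libraries. There were 65 symbols that stood on more than 1 line, on 163 lines in all, and these lines were kept apart by position. Starts equalled the 1-based RefSeq starts of GRCm38.p6 for 60.2% of the symbols found there and lay 1 base below them for 0.0581%, so coordinates are given as deposited, counted from 1, on mm10. Gene lengths were multiples of 3 for 37.7% of genes, so they include untranslated exons.

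Summed gene counts were 10862573, 9400512 and 8734906 in replicates 1 to 3 at 0 h, and 8069314, 8615595 and 9249248 in replicates 1 to 3 at 24 h. At these depths a floor of 3 counts corresponds to 0.276 to 0.372 CPM in a library. Floors and the counting intervals of summed counts cover counting error only, and treat reads copied in PCR as independent molecules. The 95% intervals of log2 changes rest on the spread between libraries. No mitochondrial genes were among the genes used here, so a mitochondrial share that had been planned was not computed.

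Genes with low counts were removed with filterByExpr at its default settings, which left 13956 genes holding at least 99.82% of each library's counts. A gene near 0 at 0 h passed this filter only through its counts at 24 h. The share of higher members among those tested is therefore partly set by the filter in lists of such genes. Libraries were scaled by TMM, and the 24 h libraries were compared with the 0 h libraries by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, two-sided, no covariate) on the deposited counts. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Every adjusted p given for a gene comes from this test unless another is named. CPM values are TMM-scaled and are given as mean ± SD of 3 libraries. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the test's F statistic, and are approximate. A gene with 0 counts in all libraries of a time is given a lower bound of its fold, computed against 3 counts over the group, and a gene with 1 to 3 counts is given a ratio of summed counts with an exact 95% counting interval.

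There were 28 gene lists, holding 505 genes of which 504 were found, and they were fixed together with the groups, the main test and most alternatives before the data were examined. They were written with knowledge that the published study stressed inflammatory genes, so the inflammatory lists are not independent of it. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the 28 lists. Members past the threshold were counted both over all genes tested and with p-values adjusted over the list alone. Shares of counts were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

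The rule for naming genes took 4 parts. It named the 6 largest rises and the 6 largest falls among called genes whose 2 groups of libraries did not overlap and whose mean CPM reached 10 in the higher group. It named the 2 members with the lowest p in each response or lens list, and the 2 members with the highest mean CPM in each list of another cell type. It always named Cxcl1, S100a9, Csf3, Ptgs2, Ccl2, Lcn2 and Hmox1, which the published study stressed, and Acta2, Fn1, Cdh1, Pax6, Foxe3, Prox1 and Mki67. Other members of a list are given as examples and were chosen after their values were seen. This gave 77 genes, of which 3 are not reported here. Some of them overlap another gene and may share its reads: Timp1 lies within Syn1, and Pfkm, Lrat, Pax6, Ogn and Angptl7 overlap Senp1, Rbm46os, Pax6os1, Cenpp and Mtor. Members of the metallothionein, crystallin, Ifit, Oas, Gbp and Sprr families have close copies, and reads could have been split between them.

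The test was checked on simulated counts for 13956 genes with the means and library sizes of these libraries, in which 200 genes were changed. It called 2% of genes changed 1.5-fold, 34% of those changed 2-fold, 78% of those changed 4-fold and 92% of those changed 8-fold. Of its 108 calls 5 were false (4.63%). These shares hold for that simulation only. Far fewer genes were changed in it than the 3942 called in the data, and fewer changed genes make the adjusted threshold stricter. Alternatives were RLE and upper-quartile scaling, library totals only, scaling without the crystallins, no low-count filter, a filter at 1 CPM, DESeq2 1.42.0, limma-voom, edgeR's exact test, a test against a 1.5-fold change (glmTreat), a replicate block, and leaving out each library in turn. Scaling without Rn45s and Lars2, a photoreceptor covariate, and the block together with an estimated correlation were added after seeing the data.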

Results

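The libraries show how the cells left on the lens capsule differ between the moment of fiber cell removal and 24 h later, a mouse model of cataract surgery. After that operation in people, the epithelial cells left behind can cloud the capsule. There were 3 libraries at each time, with 8069314 to 10862573 counts and 16248 to 16962 genes detected per library. Pearson correlations of log2 CPM across genes were 0.9877 to 0.9887 within 0 h, 0.9798 to 0.9842 within 24 h and 0.9486 to 0.9616 between times, where genes are not independent replicates. The first principal component held 65.8% of the variance and separated the times. No pair of libraries of the same time agreed within sampling noise.

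At 24 h, inflammatory genes that were near or at 0 in the fresh tissue had risen by large amounts, while genes of the lens fiber had fallen, as had Lrat, Rgr and Rpe65. Of 13956 genes tested, 3942 (28.2%) changed, 2125 of them higher and 1817 lower at 24 h. At least 2-fold changes were seen in 1269 higher and 920 lower genes. The groups of libraries did not overlap for 6237 genes (44.69%), where chance gives 10%. The biological coefficient of variation was 25.09%. Leaving out 0 h replicate 3 brought the lower genes to 1041, and testing against a 1.5-fold change left 1060 higher and 629 lower.

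The largest rises by the fixed rule were in Cxcl1, Csf3, Irg1, S100a9, Sprr1a and Egr2. Cxcl1, a chemokine that attracts neutrophils (chromosome 5, 90891245 to 90893115), had 0 counts in every 0 h library and 54.0 ± 21.1 CPM at 24 h (n = 3), at least 499-fold higher (adjusted p = 0.000178). Irg1, which makes itaconate in activated macrophages, had 0 counts at 0 h and 14.9 ± 7.46 CPM at 24 h, at least 141-fold higher. S100a9, a subunit of calprotectin, had 1 count at 0 h and 577 at 24 h, a ratio of 609 with a 95% counting interval of 109 to 24080. Egr2, a transcription factor, had 1 count at 0 h and 418 at 24 h, a ratio of 441 (78.7 to 17456). Csf3, the granulocyte colony-stimulating factor (chromosome 11, 98701313 to 98703629), went from 0.134 ± 0.153 to 181 ± 161 CPM, a log2 fold change of 10.19 ± 1.15 (SE). Sprr1a, a precursor of the cornified envelope, rose by 8.36 ± 0.40 on the log2 scale to 74.6 ± 10.02 CPM. Csf3 was past the threshold in the edgeR test (adjusted p = 0.000491) and not with limma-voom (adjusted p = 0.0744), with adjusted p from 3.07e-19 to 0.0744 over 19 alternatives. Its log2 fold change was 11.39 without 0 h replicate 1 and 9.24 without 24 h replicate 2, and the single 0 h counts of S100a9 and Egr2 were in 0 h replicate 1.

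Among the largest falls by the same rule were Lrat, Rgr, Kcne4, Rpe65 and Kynu. Lrat, Rgr and Rpe65 act in the handling of retinoids for vision. Lrat (chromosome 3, 82892582 to 82903974) fell by 5.80 ± 0.66 on the log2 scale, Rgr fell by 4.90 ± 0.36 and Rpe65 fell by 4.06 ± 0.50. Kcne4, a potassium channel subunit, went from 34.5 ± 0.663 to 1.44 ± 1.03 CPM. Kynu, which encodes kynureninase, fell 14.7-fold. On the log2 scale Lrat was at -5.21 without 24 h replicate 2 and -6.42 without 24 h replicate 3, Rpe65 at -4.66 without 24 h replicate 1, Kcne4 at -5.17 without 24 h replicate 2 and Kynu at -4.73 without 24 h replicate 3.

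Chemokines and cytokines rose almost throughout. Of 27 members tested, out of 32 listed, 26 were higher and 0 lower, and the same count held adjusted over the list alone. Ccl2, which recruits monocytes (chromosome 11, 82035577 to 82037452), went from 2.58 ± 0.585 to 258 ± 34.2 CPM, a 100-fold rise (adjusted p = 2.35e-06), and the neighbouring Ccl7 from 0.356 ± 0.0509 to 44.3 ± 2.63 CPM. Among members chosen after their values were seen, Lif reached 174 ± 121 CPM at 24 h and Csf1 261 ± 79.9 CPM, while Ccl12 was not called (adjusted p = 0.655). Of the 26 higher members 16 were highest in 24 h replicate 2, and their median log2 fold change was 5.73, and 5.28 without it. The list passed camera (adjusted p = 2.28e-39, and 0.029 with an estimated correlation). Neutrophil markers moved with it, though of 14 found only 7 passed the low-count filter. All 7 tested were higher, and 7 also adjusted over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.13 with an estimated correlation). Of the 7, S100a8 and S100a9 are also members of the acute-phase list. Itgam went from 3.70 ± 3.17 to 37.3 ± 20.6 CPM (log2 fold change 3.36, and 4.27 without 0 h replicate 3) and Csf3r from 1.98 ± 0.499 to 37.6 ± 10.7 CPM.

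Of 30 acute-phase and NF-kB response genes listed, 25 passed the low-count filter. All 25 tested were higher, also when adjusted over the list alone (camera adjusted p = 1.07e-43, and 0.00332 with an estimated correlation). Lcn2, an iron-siderophore binding protein of the acute phase (chromosome 2, 32384637 to 32387739), went from 84.4 ± 37.2 to 4782 ± 2287 CPM, a 56.6-fold rise (adjusted p = 0.000136). Bcl3, a regulator of NF-kB, rose 88.6-fold and Tnfaip2 88.7-fold. Ptgs2, the inducible cyclooxygenase (chromosome 1, 150100124 to 150108012), went from 0.611 ± 0.271 to 196 ± 149 CPM (adjusted p = 0.000204), a log2 fold change of 8.31, and 7.54 without 24 h replicate 2. Of the genes the published study stressed, Cxcl1, S100a9, Csf3, Ptgs2, Ccl2, Lcn2 and Hmox1, each was higher in all 3 libraries at 24 h than in any at 0 h, and these and the inflammatory lists are not independent evidence of direction.

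**Figure D1:**
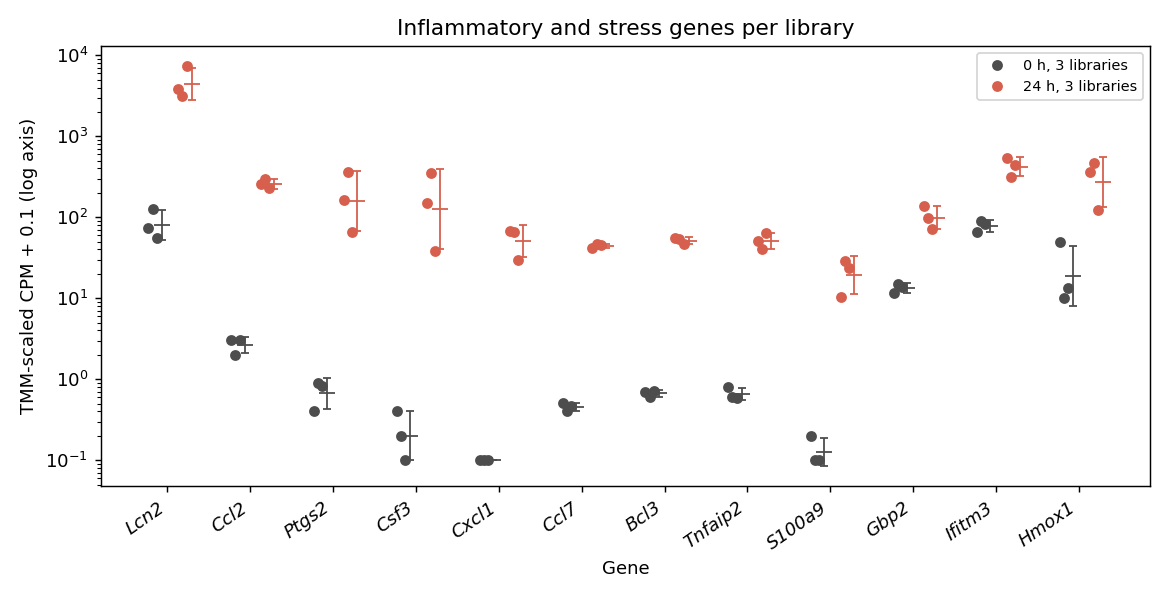
TMM-scaled CPM plus 0.1 on a log axis for 12 inflammatory and stress genes. Points are the 3 libraries at 0 h (grey) and at 24 h (red), each beside its mean and SD on the log scale, and for every gene shown the 24 h points lie above the 0 h points, with Cxcl1 at 0 counts in all 0 h libraries.

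Interferon response genes were higher in 24 of 26 members (25 adjusted over the list alone). Gbp2, an interferon-induced GTPase, rose 7.66-fold and Ifitm3, which restricts virus entry, 5.48-fold to 433 ± 112 CPM. The list passed camera (adjusted p = 7.13e-18), with adjusted p = 0.178 with an estimated correlation. Of its 24 higher members 22 were highest in 24 h replicate 1, among them Isg15, at 65.2 CPM against 22.9 and 15.7 CPM in replicates 2 and 3, and Ifi44, at 90.3 against 19.5 and 10.5 CPM, both chosen after their values were seen. Without that library, which also held the most Rn45s, 22 members were called, and the median log2 fold change of the 24 was 2.37 against 2.93. Immediate-early genes were higher in 20 of 25 members (22 adjusted over the list alone). Ier3 rose 13.7-fold and the AP-1 subunit Fosl2 3.29-fold. Of the 20 members 17 were highest in 24 h replicate 2, and their median log2 fold change was 3.66, and 3.02 without it. For that list camera gave an adjusted p of 1.66e-20, and adjusted p = 0.13 with an estimated correlation.

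Genes of the mesenchymal and fibrotic list rose in 23 of 35 members and fell in 1, and counts adjusted over the list alone were 23 and 1. Some of those that rose were already high at 0 h, such as Vim at 3171 CPM, chosen after its values were seen. Acta2, smooth muscle actin (chromosome 19, 34240336 to 34255373), went from 197 ± 64.1 to 1122 ± 442 CPM, a 5.68-fold rise (adjusted p = 0.000988). Fn1, fibronectin (chromosome 1, 71585473 to 71653234), rose 18.6-fold to 355 ± 170 CPM. Tnc, the matrix protein tenascin C, rose 86.7-fold to 734 ± 285 CPM, and Lox, which cross-links collagen, went from 2.39 ± 0.282 to 43.5 ± 10.1 CPM. The member that fell was Col1a2, a collagen chain that was chosen after its values were seen (297 CPM at 0 h, 137 CPM at 24 h) and was not called without 0 h replicate 1, 0 h replicate 3, 24 h replicate 1 or 24 h replicate 2. Camera gave an adjusted p of 9.2e-13, and adjusted p = 0.13 with an estimated correlation. Proteases and their inhibitors were higher in 13 of 19 members, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.01e-16, and 0.0259 with an estimated correlation). Plat, the tissue plasminogen activator, rose 8.74-fold and Timp1 49.8-fold.

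Lens genes fell. Of 14 crystallins tested, 7 were lower and 0 higher (8 lower adjusted over the list alone). Crygs went from 6728 ± 2520 to 2037 ± 164 CPM and Cryba2 from 4458 ± 1310 to 1613 ± 138 CPM, falls of 3.30-fold and 2.76-fold. The crystallins together held 16.0% ± 3.75 of counts at 0 h and 8.04% ± 0.974 at 24 h (n = 3 and 3), and an exact permutation test gave p = 0.1, the smallest this design allows. Other fiber genes were lower in 14 of 17 members, the same count adjusted over the list alone. Mip, the water channel of fiber membranes (chromosome 10, 128225838 to 128231811), went from 2810 ± 805 to 573 ± 130 CPM and the fiber membrane protein Lim2 from 366 ± 64.8 to 108 ± 23.4 CPM. Camera gave adjusted p = 1.28e-04 for crystallins and 1.94e-08 for other fiber genes, with adjusted p = 0.408 and adjusted p = 0.158 with an estimated correlation. Against a 1.5-fold change 9 of the other fiber genes stayed lower.

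Lens epithelial genes were lower in 12 of 18 members and higher in 0 (13 lower adjusted over the list alone). Foxe3, a transcription factor of the lens epithelium (chromosome 4, 114925147 to 114926013), went from 83.0 ± 19.97 to 28.3 ± 6.08 CPM, a 2.94-fold fall (adjusted p = 0.00145). The amino acid transporter gene Slc38a3 fell 3.09-fold and the receptor gene Fgfr3 2.92-fold. Prox1, a transcription factor of fiber differentiation, fell 2.00-fold (adjusted p = 0.00835). Pax6, the eye field regulator, had 455 ± 53.7 CPM at 0 h and 324 ± 67.5 CPM at 24 h and was not called (adjusted p = 0.0946). With a photoreceptor covariate, chosen after seeing the data, Pax6 was called lower (adjusted p = 0.0214, and from 0.0214 to 0.936 over 19 alternatives). Cdh1, epithelial cadherin, had 380 ± 73.6 and 363 ± 54.6 CPM (adjusted p = 0.833). Camera gave an adjusted p of 4.28e-06, and adjusted p = 0.172 with an estimated correlation. Against a 1.5-fold change 6 epithelial members stayed lower, and Prox1 was not called (adjusted p = 0.0821, and from 7.07e-05 to 0.0821 over 19 alternatives).

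**Figure D2:**
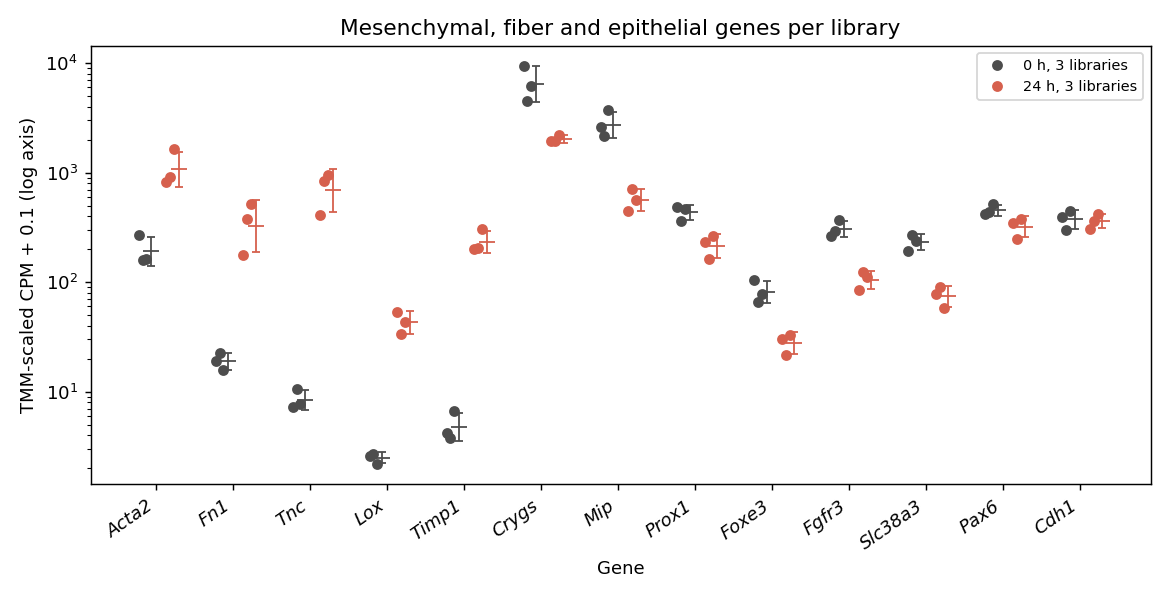
TMM-scaled CPM plus 0.1 on a log axis for mesenchymal, fiber and epithelial genes, with 3 libraries per time as points and the mean and SD on the log scale beside them. Acta2, Fn1, Tnc, Lox and Timp1 lie higher at 24 h, Crygs, Mip, Prox1, Foxe3, Fgfr3 and Slc38a3 lower, and the libraries of Cdh1 overlap.

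Basement membrane genes went both ways, with 2 higher and 7 lower of 16 (4 and 7 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.219). Lamb2, a laminin chain, fell 2.16-fold and Agrn, a heparan sulphate proteoglycan, rose 1.76-fold. The lower count was 1 without 0 h replicate 1, 0 h replicate 3, 24 h replicate 1 or 24 h replicate 2, and the higher count was 0 without 0 h replicate 1 or 0 h replicate 2 and 1 without any 24 h library. Agrn was not called against a 1.5-fold change (adjusted p = 0.274) or without 0 h replicate 1 (adjusted p = 0.0706), 0 h replicate 2 (adjusted p = 0.0627) or 24 h replicate 1 (adjusted p = 0.0638), with adjusted p from 0.00334 to 0.274 over 19 alternatives.

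Cell cycle genes were higher in 6 and lower in 1 of 28, the same adjusted over the list alone (camera adjusted p = 0.306). The 6 were Mcm2, Mcm3, Mcm4, Mcm5, Mcm6 and Pcna, which act in DNA replication. Mcm6 rose 4.59-fold to 37.6 ± 18.1 CPM and Pcna 2.08-fold. All 6 were highest in 24 h replicate 3, and their median log2 fold change was 1.71, and 1.20 without it. Aurka, a mitotic kinase, was the lower member and was not called when any single library was left out. Mki67, a proliferation marker, had 26.5 ± 13.2 and 17.1 ± 11.2 CPM and was not called (adjusted p = 0.412), but was called lower with the photoreceptor covariate (adjusted p = 0.0147, and from 0.0147 to 0.866 over 19 alternatives). Genes of p53 signalling and apoptosis were higher in 12 and lower in 3 of 19 (13 and 3 adjusted over the list alone). Cdkn1a, a cell cycle inhibitor, rose 24.1-fold and Phlda3 4.99-fold, and the lower members, named after their values were seen, were Sesn1, Trp53inp1 and Bcl2. Camera gave an adjusted p of 0.0151, and adjusted p = 0.178 with an estimated correlation. Against a 1.5-fold change 6 p53 and apoptosis members stayed higher.

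Stress and biosynthetic genes rose in several lists. NRF2 and oxidative stress genes were higher in 12 and lower in 1 of 22, the same adjusted over the list alone, and Mt2 rose 41.0-fold, Mt1 13.8-fold and the heme oxygenase gene Hmox1 12.9-fold to 315 ± 176 CPM (log2 fold change 3.69, and 4.80 without 0 h replicate 1). Genes of the unfolded protein and amino acid response were higher in 18 and lower in 2 of 25 (18 and 3 adjusted over the list alone), with Asns up 7.69-fold and Manf 3.59-fold, and 16 of the 18 were highest in 24 h replicate 2 (median log2 fold change 1.16, and 1.09 without it). Ribosome biogenesis genes were higher in 19 of 22 (20 adjusted over the list alone), with Npm1 up 2.74-fold and Utp20 2.43-fold. Camera gave adjusted p = 1.63e-07, 1.52e-06 and 9.98e-10 for these 3 lists, with adjusted p = 0.148, adjusted p = 0.243 and adjusted p = 0.145 with an estimated correlation. The lower NRF2 member, Gclc, was not called without 0 h replicate 1, 0 h replicate 3, 24 h replicate 1 or 24 h replicate 2, and the lower unfolded protein count was 1 without 0 h replicate 1. Against a 1.5-fold change 11 unfolded protein and 10 ribosome biogenesis members stayed higher.

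Cholesterol synthesis genes were higher in 11 of 17, with 11 higher and 1 lower adjusted over the list alone, and Msmo1, an enzyme of sterol synthesis, rose 3.66-fold. Growth factor signalling genes were higher in 11 of 15, with 12 higher and 1 lower adjusted over the list alone, and the EGF receptor ligands Tgfa and Hbegf rose 2.24-fold and 4.07-fold. Heat shock genes were higher in 5 of 14 (10 adjusted over the list alone), with Bag3 up 2.21-fold and Hspd1 2.06-fold. Camera gave adjusted p = 1.28e-04, 5.73e-05 and 7.92e-04 for these lists, with adjusted p = 0.408, adjusted p = 0.13 and adjusted p = 0.221 with an estimated correlation. Glycolysis genes were higher in 1 and lower in 1 of 16, the same adjusted over the list alone (camera adjusted p = 0.958), with Hk2 up 1.91-fold and Pfkm down 1.91-fold. The cholesterol count was 7 without 0 h replicate 2, and the heat shock count was 8 without 0 h replicate 1 and 9 with library totals only. Glycolysis members were 3 higher without 24 h replicate 3 and 2 lower without 24 h replicate 2. Hk2 was not called without 0 h replicate 3 (adjusted p = 0.0615, and from 0.00127 to 0.158 over 19 alternatives), and against a 1.5-fold change neither Hk2 nor Pfkm was called (adjusted p for Pfkm from 2.11e-05 to 0.0565).

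**Figure D3:**
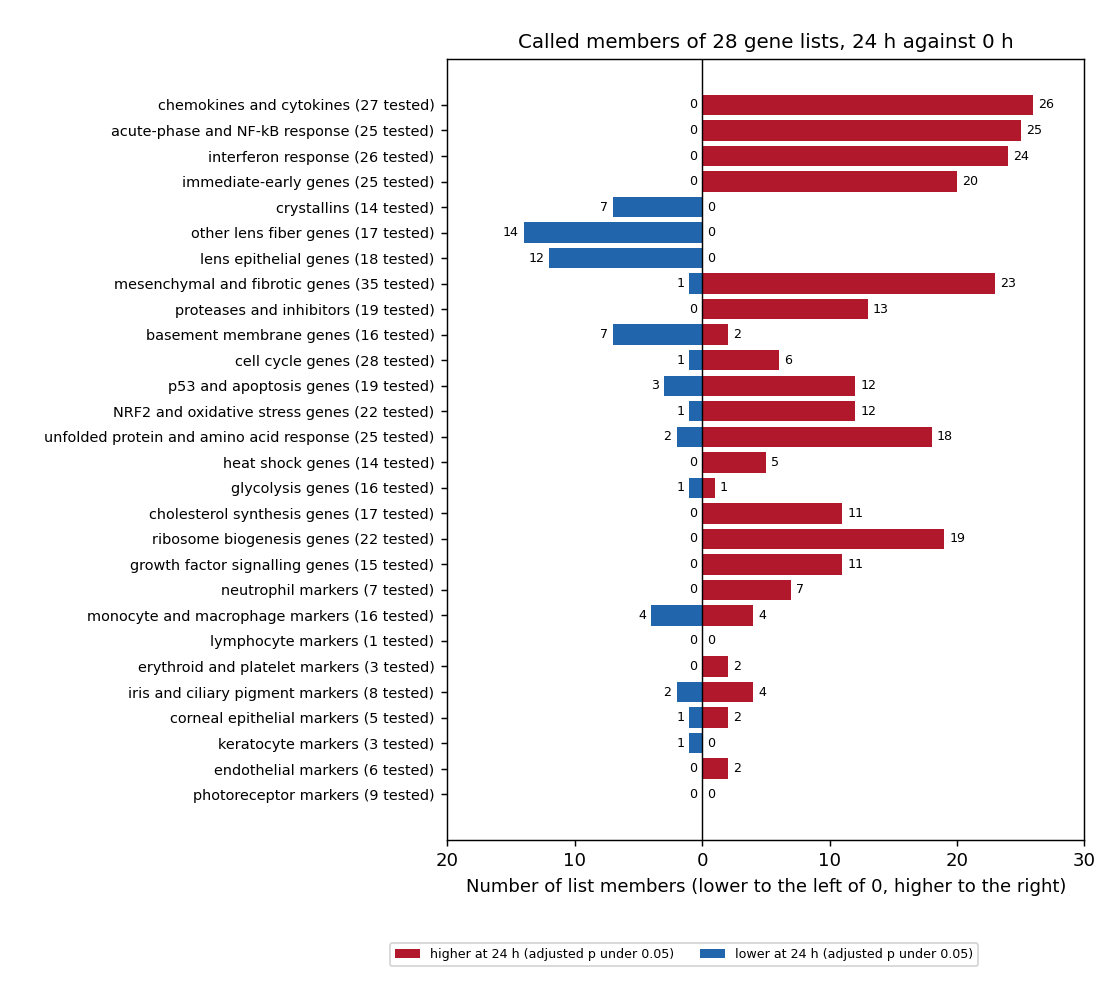
Number of members called higher (red, to the right) or lower (blue, to the left) at 24 h in each of 28 gene lists, with the number tested beside each name. The acute-phase and NF-kB list has 25 of 25 higher and the list of other lens fiber genes 14 of 17 lower.

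Markers of other cell types were measured beside these groups. Monocyte and macrophage markers went both ways, 4 higher and 4 lower of 16 (4 and 5 adjusted over the list alone, camera adjusted p = 0.958), and the list's median was below 0 while its mean and test direction were above it. Lyz2 had 16.3 ± 4.13 CPM at 0 h and 29.5 ± 17.6 CPM at 24 h and was not called (adjusted p = 0.142), except as higher without 24 h replicate 2 (adjusted p = 0.0488, and from 0.0488 to 0.543 over 19 alternatives). Csf1r, the receptor for macrophage growth factor, fell 2.54-fold (adjusted p = 0.0406). It was not called with limma-voom, against a 1.5-fold change, or without 0 h replicate 2, 0 h replicate 3, 24 h replicate 1 or 24 h replicate 2 (adjusted p from 0.00699 to 0.149 over 19 alternatives). The list's lower count was 2 without any of these 4 libraries. Of erythroid and platelet markers, 2 of 3 were higher, also adjusted over the list alone (camera adjusted p = 0.112), with Alas2 up 6.83-fold and Pf4 not called (58 counts at 0 h and 74 at 24 h, adjusted p = 0.769). The only lymphocyte marker tested, Lck, had 1.33 ± 0.789 and 2.20 ± 0.811 CPM (adjusted p = 0.408, camera adjusted p = 0.796).

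Of iris and ciliary pigment markers, 4 were higher and 2 lower of 8 (5 and 2 adjusted over the list alone, camera adjusted p = 0.84). Dct, a melanin synthesis enzyme, went from 47.3 ± 25.2 to 269 ± 213 CPM (adjusted p = 0.0263), and Tyrp1 had 71.9 ± 13.1 and 174 ± 153 CPM (adjusted p = 0.217). Tyrp1 was called higher without 24 h replicate 2 (adjusted p = 0.0046, and from 0.0046 to 0.659 over 19 alternatives). The lower members were Rpe65 and Oca2. The higher count was 0 without 0 h replicate 1, 0 h replicate 3 or 24 h replicate 1, 2 without 24 h replicate 3 and 6 without 24 h replicate 2. It was 1 with limma-voom, 0 against a 1.5-fold change and 2 with the photoreceptor covariate. Dct was not called against a 1.5-fold change or without 0 h replicate 1, 0 h replicate 3 or 24 h replicate 1, with adjusted p from 0.00155 to 0.0847 over 19 alternatives.

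Photoreceptor markers were present at both times, and 0 of 9 were called over all genes tested by edgeR or adjusted over the list alone (camera adjusted p = 0.306). At an unadjusted p under 0.05 only Opn1sw passed (p = 0.0198 in edgeR's test over all genes), and edgeR's exact test called 1, DESeq2 0 and limma-voom 0. With the replicate block 6 of 9 were called lower. Gnat1, the rod transducin subunit, had 893 ± 488 and 702 ± 472 CPM. Corneal epithelial markers were higher in 2 and lower in 1 of 5 (3 and 1 adjusted over the list alone, camera adjusted p = 0.84). Aldh3a1 fell 2.04-fold (adjusted p = 0.0279) and Krt15 had 8.37 ± 0.743 and 24.8 ± 23.1 CPM (adjusted p = 0.0744). The corneal higher count was 0 without any single 0 h library or 24 h replicate 1, and Aldh3a1 was not called against a 1.5-fold change or without 0 h replicate 1, 24 h replicate 1 or 24 h replicate 2 (adjusted p from 0.00183 to 0.161 over 19 alternatives). Of keratocyte markers 1 of 3 was lower (2 adjusted over the list alone, camera adjusted p = 0.112), Ogn, which fell 3.45-fold, and Angptl7 had 13.6 ± 9.46 and 3.96 ± 2.81 CPM. Angptl7 was not called by edgeR's quasi-likelihood test, and was called lower without 0 h replicate 2 or 24 h replicate 3, with no low-count filter, with DESeq2, with the exact test and with the photoreceptor covariate (adjusted p from 0.0163 to 0.275 over 19 alternatives). Krt15 was called higher without 24 h replicate 2 or 24 h replicate 3, with no low-count filter, with DESeq2 and with the exact test (adjusted p from 0.0136 to 0.258). Its level was 51.4 CPM in 24 h replicate 1 against 9.35 and 13.6 CPM in replicates 2 and 3, and it was not called without replicate 1. The keratocyte count was 2 without 0 h replicate 2 or 24 h replicate 3. Of endothelial markers 2 of 6 were higher, also adjusted over the list alone (camera adjusted p = 0.306), and 1 without 0 h replicate 1 or 24 h replicate 1, while Kdr had 24.9 ± 12.8 and 11.8 ± 6.91 CPM and Egfl7 9.95 ± 4.53 and 5.51 ± 1.32 CPM. Kdr was called lower without 0 h replicate 3 (adjusted p = 0.0494, and from 0.0151 to 0.415 over 19 alternatives) and Egfl7 without 0 h replicate 2 (adjusted p = 0.0427, and from 0.0427 to 0.495).

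**Figure D4:**
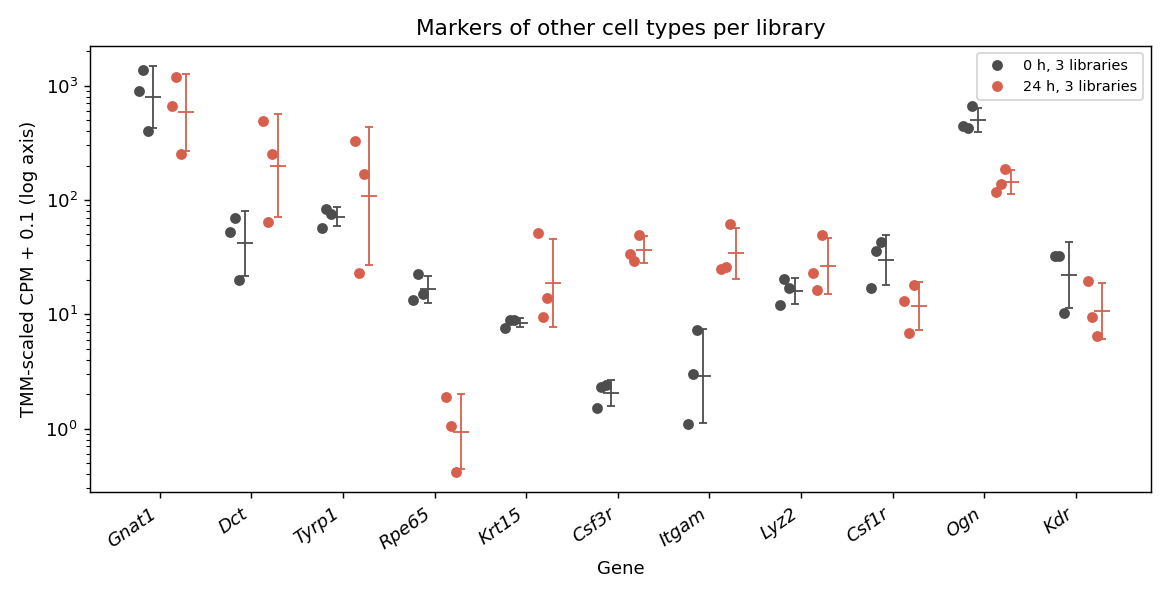
TMM-scaled CPM plus 0.1 on a log axis for markers of other cell types and Rpe65, with 3 libraries per time as points and the mean and SD on the log scale beside them. Csf3r and Itgam lie higher at 24 h and Rpe65 and Ogn lower, while the libraries of Gnat1, Tyrp1, Lyz2 and Kdr overlap between times.

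Over the 28 lists, camera with the preset correlation called 17 lists, 14 up and 3 down. With an estimated correlation it called 3 lists, those of chemokines and cytokines, acute-phase and NF-kB genes, and proteases and inhibitors. Fry, which tests whether a list's genes move on balance in a single direction without comparing them with other genes, called 18 lists, 15 up and 3 down. Its 3 lists down differed from camera's: crystallins did not pass (fry adjusted p = 0.0677) and keratocyte markers did (fry adjusted p = 0.0209). Ribosomal RNA precursor Rn45s held 2.83% ± 0.538 of counts at 0 h and 8.49% ± 6.02 at 24 h (exact permutation p = 0.1, n = 3 and 3), with 15.4% in 24 h replicate 1. The 20 highest genes of each library held 24.4% ± 3.05 and 22.3% ± 5.23 of counts (exact permutation p = 0.6, n = 3 and 3).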

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

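The alternatives added after the result was seen were scaling without Rn45s and Lars2, the photoreceptor covariate, and the replicate block with an estimated correlation. Calls shared with the edgeR quasi-likelihood test had the same direction under every alternative. The number of changed genes, 3942 in that test, was 3947 with RLE scaling, 4015 with upper-quartile scaling, 3764 with library totals only, 3975 without crystallins and 3961 without Rn45s and Lars2. It was 3936 with no low-count filter, 3948 with a filter at 1 CPM, 4310 with DESeq2, 3892 with limma-voom, 4311 with edgeR's exact test and 4276 with the photoreceptor covariate. A test against a 1.5-fold change gave 1689, with 1060 higher and 629 lower, of which 608 lower genes were also past 2-fold, because it asks for a larger change. Leaving out each library gave 2717 to 3545 changed genes and 1041 to 1648 lower genes against 1817, with fewer samples in each fit. The difference in crystallin share, -7.99 percentage points, ranged from -9.57 to -5.92 when single libraries were left out.

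With an estimated correlation camera called 3 lists in place of 17. The correlation was preset at 0.01 and estimated at 0.00497 to 0.175 in the 3 lists kept. For the acute-phase and NF-kB list the estimate, 0.00497, lay below the preset value. Its unadjusted camera p still went from 3.83e-45 to 0.000118. The size of the correlation alone therefore cannot account for the weaker p-values of the second run. Among lists lost, the estimate was 0.766 for crystallins and 0.699 for interferon genes, but 0.0267 for p53 and apoptosis genes. Same-numbered libraries correlated at 0.0866, 0.215 and 0.397 in their deviations from the group means, and differently numbered ones at -0.35 to 0.172. The highest of the latter was 24 h replicate 1 with 0 h replicate 2. The numbers are not said to mark shared animals or days, so pairing is neither shown nor excluded. Both the unpaired test and the replicate block are therefore given. The replicate block moved the changed genes to 4489, of which 3849 were shared, and the lists called by camera to 19. It moved lower crystallins from 7 to 13, higher heat shock genes from 5 to 9 and lower photoreceptor markers from 0 to 6, and higher pigment markers from 4 to 2. Pax6, Kdr and Angptl7 were called lower with the block (adjusted p = 0.041, 0.0151 and 0.0414, with ranges over 19 alternatives of 0.0214 to 0.936, 0.0151 to 0.415 and 0.0163 to 0.275). The block with an estimated correlation called 0 lists. The cause was not tested.

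Genes that were not called changed sign in some settings. Pf4, 0.35 on the log2 scale, was -0.27 to 1.08 when single libraries were left out, below 0 without 0 h replicate 1 or 24 h replicate 3, and -0.18 with the photoreceptor covariate. Gnat1, -0.35, was -0.97 to 0.11, above 0 without 0 h replicate 2 or 24 h replicate 3, and 0.20 with the covariate. Cdh1, -0.07, was 0.030 with library totals only and -0.21 to 0.090 with single libraries left out, above 0 without 0 h replicate 3 or 24 h replicate 1. The cause was not tested. Of 74 named genes, 8 lost a call and 8 gained a call under at least 1 alternative. In simulated data at this depth, where 200 of 13956 genes were changed, 2% of genes changed 1.5-fold were called, a share that holds for that simulation only.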

Other observations

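The tests in this part were chosen after the result was seen, except the count of splits. The genes in this paragraph and the next were picked after their values were seen. Krt16 had 0 counts at 0 h and was at least 96.0-fold higher at 24 h, and Krt17 reached 15.4 CPM from 0.351. Ecm1 and Anxa8 rose by 5.48 ± 0.38 and 6.52 ± 0.48 on the log2 scale. Grem1, a secreted BMP antagonist, had 2.20, 1.90 and 3.17 CPM at 0 h and 811, 200 and 548 CPM in replicates 1, 2 and 3 at 24 h (adjusted p = 8.85e-05). Gpnmb had 38.0, 78.4 and 31.6 CPM at 0 h and 1165, 480 and 1090 CPM at 24 h.

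Abca8a and Abca9 fell by 3.34 ± 0.45 and 3.12 ± 0.29 on the log2 scale. Col9a1, Best2, Pdyn and Slc39a12 fell by 2.83 ± 0.26, 2.80 ± 0.36, 2.81 ± 0.28 and 2.80 ± 0.50. Lars2 had 21770 CPM in 24 h replicate 1 against 6464 and 5992 in the other 24 h libraries, the library with the high share of Rn45s. Xist had 510, 9.22 and 3587 CPM at 0 h and 371, 1507 and 399 CPM at 24 h, and the Y-linked Ddx3y 42.8, 54.5 and 0.610 CPM at 0 h and 43.5, 12.1 and 39.2 CPM at 24 h. The labels used here give no sex. Both genes differed widely between libraries of the same time, so the libraries may differ in sex, which the test did not model.

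Of the 10 splits of the 6 libraries into 3 and 3, only the real split, 1 of 10, called as many genes by edgeR's quasi-likelihood test (3942). The highest of the other splits called 0, with 50 to 630 genes at an unadjusted p under 0.05 against 5571 for the real split. With 10 splits the share cannot fall under 0.05. Every other split puts libraries of both times in each group, so a difference between times adds to the spread within its groups. Their low counts therefore do not show how many genes would be called without such a difference.

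The rise of Lcn2 and of the chemokines may come from lens cells or from leukocytes that entered by 24 h. S100a8, S100a9 and Lyz2, taken as abundant transcripts of neutrophils and macrophages, together rose by 44.0 CPM, which is 0.936% of the rise of Lcn2 and 2.23% of the summed rise of the called chemokines and cytokines (1970 CPM). These 3 may follow leukocytes poorly here, since Lyz2 was not called. Csf3r and Itgam reached 37.6 and 37.3 CPM, each above S100a9, but CPM are not divided by gene length. S100a9 is 524 bases long, and Csf3r and Itgam are 4047 and 4682, so these levels do not rank numbers of transcripts. The CPM shares and comparisons between genes in this paragraph have the same limit. All 14 neutrophil and macrophage markers whose mean rose gained 203 CPM together, 4.33% of the rise of Lcn2 and at most 5.43% in a 24 h library. That argues against leukocyte RNA as the source of most of it unless leukocytes hold many times more Lcn2 than these markers together. The ratio of Lcn2 to the markers in leukocytes was not measured. For the chemokines and cytokines the same markers came to 10.3%, and to 19.3% in 24 h replicate 3, and 15 of 26 called members, such as Il1b, Ccl3 and Tnf, rose by fewer CPM than the 3 transcripts together. Their source cannot be told apart, because those levels leave room for leukocytes. Scaling does not account for the list, since 26 members stayed higher under each of 5 other scalings.

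The fall of lens genes could reflect fiber cells left at 0 h and lost by 24 h, dilution by other cells, scaling, or a change in the epithelial cells. Loss of residual fibers would leave in place genes that fibers lack, and 12 of 18 epithelial list genes were lower. At least 9 stayed lower under each of 5 other scalings. Whether fibers held some of these genes was not measured, so the 12 calls cannot exclude loss of fibers. Dilution by cells without these genes would move all members alike. For 9 of 18 the 95% interval left out the list's median of -0.784 on the log2 scale, with Npnt at -2.35 and Cdh1 at -0.07. That argues against such dilution as the only cause. Dilution as a part of the fall, or by cells that hold some members, stays open. For the crystallins and fiber genes, loss of residual fibers stays open, because the fiber-enriched Crygb, Crygc, Crygd and Cryge had a median of -1.67 with a median SE of 1.67. A change in the epithelial cells between the times was not tested and stays open.

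The fall of Lrat, Rgr and Rpe65 might come from less retina or pigmented tissue in the 24 h samples. The mean log2 CPM of 9 photoreceptor markers was 7.362, 8.11 and 6.221 in the 0 h libraries and 6.88, 7.494 and 5.418 in the 24 h libraries. The difference was -0.634, with a 95% lower bound of -2.92. Less retina as the whole cause would lower Lrat, Rgr and Rpe65 only as far as these markers, if all came from the same tissue. The change in their mean log2 CPM less that of the markers was -3.85, with a 95% upper bound of -1.66. With a single library left out the upper bound was at most -0.715. Lrat, Rgr and Rpe65 were named for being among the largest falls, and the bound does not allow for that choice. The gap therefore cannot decide it, and less retina as the whole or a part of the fall stays open. A joint loss of pigmented tissue would lower the pigment markers together. Of 8 markers 4 were called higher, but 1 with limma-voom and 0 against a 1.5-fold change or without 0 h replicate 1, 0 h replicate 3 or 24 h replicate 1, so that count alone is weak. The 95% intervals of 6 of the 7 other pigment markers, all but Oca2, lay above that of Rpe65, as did 6 with any single library left out. Rpe65 was named for being among the largest falls, so most other genes would lie above it. The intervals therefore cannot decide on a joint loss. Less of a pigmented tissue that holds Rpe65, with more of another that does not, was not tested and stays open. All 4 called melanosome genes were low in 24 h replicate 2 (Dct 63.7 CPM against 489 and 254), a pattern that more pigmented tissue in the other 24 h libraries could give. The order of these libraries was seen before that test was chosen, so carry-over and a rise in resident cells cannot be told apart here.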
